A study of Homo sapiens with 47 samples.

How the data were processed

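Blood had been collected into heparin, and the mononuclear cells had been separated and put into Trizol within hours, per the labels' protocols. RNA was amplified and biotin-labelled with a Nugen Ovation kit and hybridized to Affymetrix arrays, per the labels' protocols. The deposited values are probe set intensities on a linear scale, made with RMA, which corrects the background, normalizes by quantiles and summarises the probes of a set, per the submitters' processing notes; its version and settings are not given in the sources used here. The table held 54675 probe sets for 47 samples, with intensities from 3.52 to 24103 and array medians from 16.4 to 18.5. The highest correlation between any 2 arrays was 0.9942, so no array was treated as a duplicate of another. The table used here gives no detection calls, so no probe set was called absent, and quantile normalization forces a common distribution on all arrays, which can turn a rise of many genes in part of the samples into small falls elsewhere. RMA values near the background are compressed, so differences of dim genes such as AHSP in controls are understated.

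The samples were grouped by their labels into 17 sJIA patients and 30 normal controls, each a separate donor, so p-values reflect the spread between donors. The labels used here give no pairing of patients with controls, batch or covariate. Intensities were taken to log2, a step foreseen for the case that the table was linear. The 62 Affymetrix control probe sets were left out. Of the others, 41091 had exactly 1 gene symbol in the platform annotation used here, 1801 had several and 11721 had none. Entrez IDs matched the RefSeq gene table for 41037 of the 41091, and 0 symbols needed an update. Each of 19775 genes was represented by its brightest single-symbol probe set, by the mean over all 47 arrays, with no filter on intensity.

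Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over the 19775 genes and a threshold of 0.05 on the adjusted p. Median log2 difference of all genes was 0.0149. Before the data were examined, 28 gene lists were fixed, 14 of cell types and 14 of pathways, with 360 genes, of which 333 had a probe set of their own (the measured members) and 2 (PRF1 and CD163) stood in more than 1 list. The cell type lists were T cell, NK receptor, cytotoxic granule, B cell, plasma cell, classical monocyte, nonclassical monocyte, dendritic cell, mature neutrophil, immature granulocyte, erythroid, fetal and embryonic globin, platelet and progenitor. The pathway lists were heme synthesis, cell cycle, inflammasome and IL-1 family, Toll-like receptor signalling, IL-6 and STAT3 response, S100 alarmins, type I interferon response, interferon gamma response, MHC class II, MHC class I presentation, hemophagocytic lymphohistiocytosis genes, macrophage scavenging and iron, NF-kB targets and immediate early genes. A list needed 3 measured members, which left 27 to test; for each, the difference between groups of the mean over members was tested by permuting sample labels 100000 times, two-sided, with Benjamini-Hochberg adjustment over the 27. This keeps the correlation between members but asks only whether the list's mean differs, while camera, run with a preset correlation of 0.01 and with an estimated one, compares a list with the other genes. Permuting labels also takes the spread as equal in both groups. Where the smaller patient group spread more than the controls, its p-values for the mean can be too small. limma likewise fits a single spread per gene to both groups, so its SEs and p-values can be too small for such genes. ALAS2, for instance, had an SD of 2.757 in patients and 0.7897 in controls. With the spread estimated per group, by a factor shared by all genes, 2338 genes passed, against 2838 in the main fit. The spread within groups was tested by permuting absolute deviations of the list means from the group median. Of the tested lists, 19 passed, 15 higher and 4 lower in sJIA; camera with the preset correlation passed 17 and with an estimated correlation 0, where the smallest adjusted p was 0.0534. Another 8 lists, given among the other observations, were written after these results but before their list values were seen. Their members NCR3, CEBPD and XBP1 already stood in the first lists, so the values of these genes were known.

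The rule for named genes was also fixed before the data were examined. It took the 15 genes with the largest rise and the 10 with the largest fall past the test, up to 3 members of each list with the largest change in the direction of most passing members and the 1 with the largest change the other way, and IL1B, IL6, IL18, TNF, CD163 and PRF1 whatever their result. Sex-linked marker genes, immunoglobulin and T cell receptor segments, and genes with common inherited absence or probe-affecting variation were not named under the first part. List members outside this rule are named as examples that did not pass, or to complete a count, and were chosen after their values were seen. No named gene had another probe set past the test in the opposite direction.

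Alternatives covered the probe set rule, a filter on dim genes, renormalization, centring, an added constant of 16 before log2, the variance model, array weights, RNA quality ratios or marker list means as covariates, the sample set, equal group sizes, leaving out each sample and other list tests. For the probe set rule, 1 alternative dropped probe sets with names ending in _x_at or _s_at wherever the gene had another. It went by the name alone, among probe sets with 1 gene symbol. Leaving out the arrays with a median correlation under 0.97 was added after seeing the data. With the marker lists as covariates the fit asks for a difference at equal marker levels, and since the erythroid mean alone accounts for 49.4% of the variance of the group variable, standard errors grew by a median factor of 1.4. For the 7 lists together these were 73.8% and 1.81.

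The procedure was tested on simulated data for the 19775 genes in the same 17 and 30 arrays. It recovered 82% of genes changed by 0.5 and 100% of genes changed by 1 on the log2 scale, with 4.9% of calls on unchanged genes. An erythroid list raised by 1 was estimated at 1.11, an NK receptor list lowered by 0.5 was estimated at -0.534, and 0 of 25 unchanged lists passed. The spread test found the list whose deviations had been tripled and 0 others. The simulated noise was normal and independent between genes, with the same SD in both groups. These rates therefore do not cover lists with correlated members or groups of unequal spread, as in the real data.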

Results

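Gene expression was measured on Affymetrix arrays in peripheral blood mononuclear cells (PBMC) from 17 patients with new-onset, untreated systemic juvenile idiopathic arthritis (sJIA) and 30 normal controls. sJIA is a childhood arthritis with systemic inflammation, and PBMC are the lymphocytes, monocytes and other light cells that collect above the red cells and most granulocytes on a density gradient. There was 1 array per sample, so the comparison rested on 47 arrays, whose number limits the precision. Median probe set intensities ranged from 16.4 to 18.5 across arrays. No batch is named in the labels used here, but the label codes of 6 controls began differently from those of all the patients. Some patients also had codes with a start that no control code had. Differences are sJIA minus control on the log2 scale, given for genes with the standard error (SE) and for lists of genes as the difference of the mean over members. Every difference compares n = 17 patients with n = 30 controls. Adjusted p-values are Benjamini-Hochberg values, from limma over 19775 genes for a gene and from two-sided permutation of the sample labels over 27 lists for a list.

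The comparison asked how the mononuclear cells of untreated patients differ from those of healthy donors. The largest rises in sJIA were in genes of the red cell lineage: ALAS2, the erythroid enzyme that starts heme synthesis, was 18.9-fold higher (log2 difference 4.24 ± 0.51, SE). The anion exchanger SLC4A1, the carbonic anhydrase CA1 and the globin HBD were each about 12-fold higher. Neutrophil granule genes such as OLFM4 and DEFA4, the acute-phase gene HP and the STAT3 target SOCS3 also rose. The largest falls were in ALDH1A1, an aldehyde dehydrogenase (-1.95 ± 0.25), PRSS23, a serine protease (-1.68 ± 0.24), and PID1 (-1.64 ± 0.21). The natural killer (NK) cell receptor CD160 was lower by -1.31 ± 0.25. In limma, 2838 genes had an adjusted p under 0.05, of which 1357 were higher and 1481 lower in sJIA. With each array centred on its median gene, the split was 947 higher and 2053 lower of 3000. Of the 2838 genes, 695 changed by at least 1.5-fold, 505 higher and 190 lower, and 184 rose and 36 fell by at least 2-fold.

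The 15 genes with the largest rise were ALAS2, CA1, HBD, SLC4A1, AHSP, EPB42, SELENBP1, HBM, TRIM10, OLFM4, GMPR, MYL4, ANXA3, TRIM58 and DEFA4. Their log2 differences ran from 4.24 down to 2.53, with adjusted p from 1.2e-07 to 0.000934. Of these, MYL4 and ANXA3 lay above the control median in 17 of 17 patients, ALAS2, SLC4A1, HBM, GMPR and DEFA4 in 16, and OLFM4 in 12. The 10 genes with the largest fall were ALDH1A1, PRSS23, PID1, CACNA2D3, ARPIN, ADAMTS5, LINC00996, A2M-AS1, LDB2 and CD160. Their differences ran from -1.95 to -1.31, with adjusted p up to 0.000754. PID1, CACNA2D3 and LDB2 lay below the control median in all 17 patients. The choice of probe set decided part of these values. Without _x_at or _s_at probe sets, where the gene had another, ALAS2 was at 0.04 (adjusted p = 0.539), CA1 at -0.018 (adjusted p = 0.908) and LDB2 at -0.13 (adjusted p = 0.203). With the median over a gene's probe sets ARPIN was at -0.047 (adjusted p = 0.712), PID1 at -0.26 (adjusted p = 0.0701) and TRIM10 at 0.21 (adjusted p = 0.0168). PRSS23 (-0.48), ALAS2 (2.14), CA1 (1.78) and LDB2 (-0.73) changed less there but still passed.

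**Figure D1:**
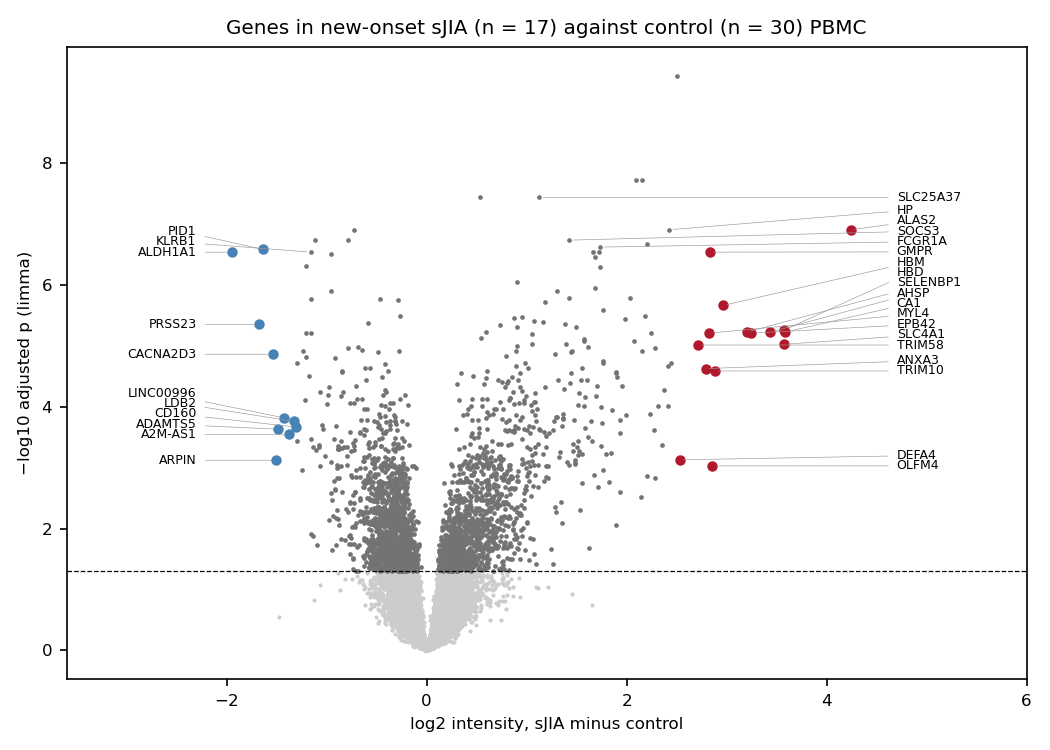
Each point is a gene, with the log2 intensity difference (sJIA minus control) on the x axis and -log10 of limma's adjusted p on the y axis. The dashed line marks an adjusted p of 0.05, large red and blue points are the 15 largest rises and 10 largest falls, and the other labelled points are list members. Red cell genes such as ALAS2 (4.24) lie farthest to the right, and ALDH1A1 (-1.95) farthest to the left among the genes past the line.

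Erythroid genes rose together. Of 21 measured members of the list fixed for this lineage, 19 rose, none fell and CA2 and SPTB did not pass. Adjusted over the list alone, 21 of 21 rose. The list mean was 7.33 ± 1.70 (SD) in sJIA and 5.2 ± 0.39 in controls, a difference of 2.13 (adjusted p = 5.4e-05, which rests on the smallest p the permutations can give, 1e-05). On this mean 16 of 17 patients lay above the control median and 11 above the highest control. Among patients 4 to 9, whose codes began like those of most controls, only patient 7 (7.069) lay above the highest control. With an estimated correlation between members the adjusted p = 0.0534. Examples were ALAS2 (4.24 ± 0.51), CA1 (3.58 ± 0.53) and HBD, the delta chain of adult hemoglobin (3.58 ± 0.53), with adjusted p of 1.2e-07, 5.9e-06 and 5.5e-06. In the heme synthesis list, FECH, which inserts iron into the ring (1.71 ± 0.29, adjusted p = 4.6e-05), and the mitochondrial iron importer SLC25A37 (1.13 ± 0.13, adjusted p = 3.6e-08) rose, SLC25A37 by 2.70 with the median over its 10 probe sets. The other 7 of 9 members, mostly enzymes of the pathway, did not pass, with the same counts adjusted over the list alone. The mean of that list was 0.36 higher (adjusted p = 0.000135, and adjusted p = 0.202 with an estimated correlation). With the erythroid mean as a covariate, the heme difference was 0.06 and FECH was at -0.092. The fetal gamma globins HBG1 and HBG2 share 3 probe sets, which the rule of 1 gene symbol left out of the gene comparison. In the fit of all probe sets these rose by 3.26 ± 0.55, 3.25 ± 0.55 and 2.75 ± 0.45 (adjusted p of 6.8e-05, 6.1e-05 and 4.3e-05), looked up after their values were seen. The names of all 3 end in _x_at, and whether they also read other globins such as HBD was not tested. The embryonic globins HBE1 (0.27 ± 0.06, adjusted p = 0.00339) and HBZ (0.14 ± 0.06, adjusted p = 0.116) lay near the low end of the intensities, and were too few for a test of the list. Progenitor genes went both ways. MYB rose (0.33 ± 0.09, adjusted p = 0.00845, and 0.20 with the median over its probe sets). The stem cell factor receptor KIT (-0.62 ± 0.10, adjusted p = 2.3e-05) and SPINK2 (-0.47 ± 0.14, adjusted p = 0.021) fell, and 5 of 8 did not pass. KIT was dim, with means of 3.345 in sJIA and 3.965 in controls. Adjusted over the list alone, 3 progenitor genes rose and 3 fell, and the list mean differed by -0.07 (adjusted p = 0.47).

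**Figure D2:**
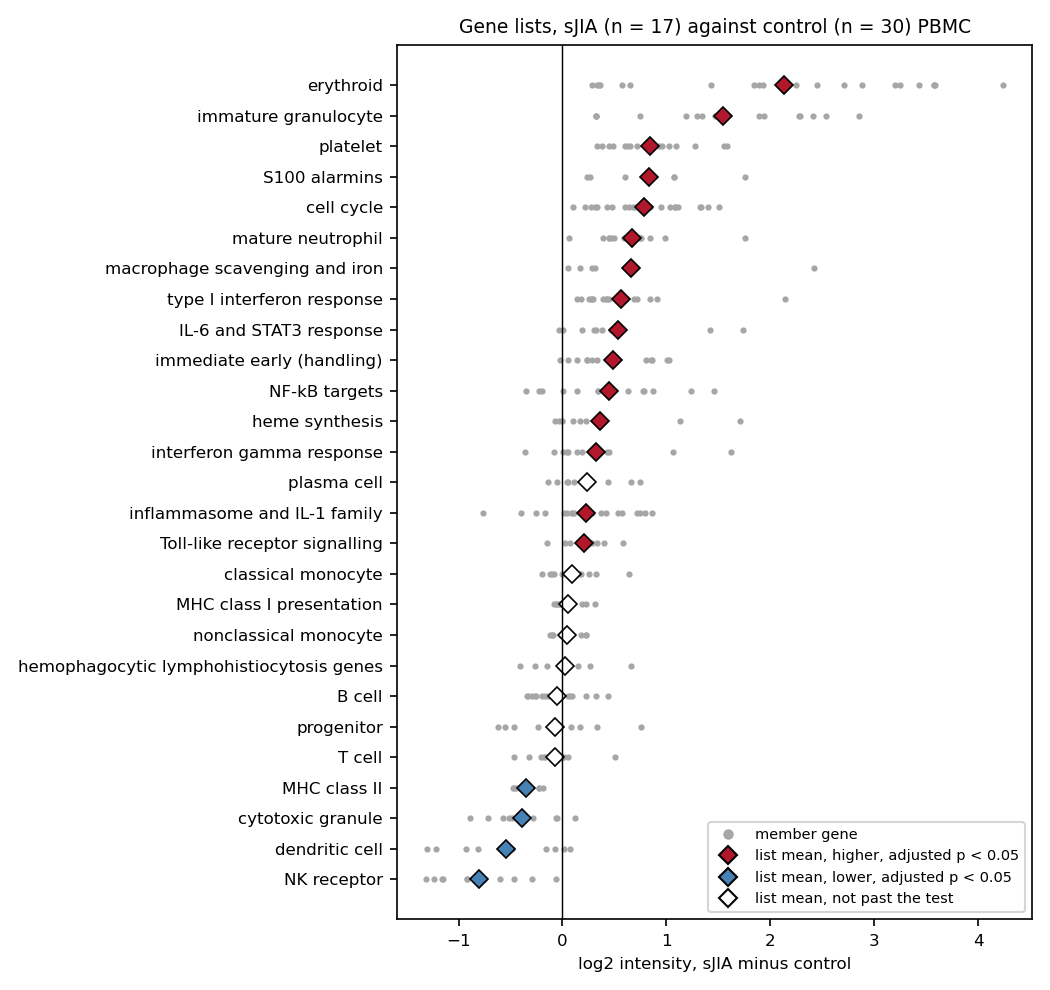
For each of 27 gene lists, gray points are the log2 differences (sJIA minus control, x axis) of the measured members and the diamond is the difference of the list mean, filled red (higher) or blue (lower) where the permutation test had an adjusted p under 0.05. The erythroid list is highest at 2.13 and the NK receptor list lowest at -0.80.

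Genes of granule formation in immature neutrophils rose in 14 of 16 measured members, with none falling, and in 15 of 16 when adjusted over the list alone. OLFM4 (2.86 ± 0.61, adjusted p = 0.000934), the defensin DEFA4 (2.53 ± 0.53, adjusted p = 0.000743) and the collagenase MMP8 (2.41 ± 0.43, adjusted p = 9.5e-05) were the largest. Their list mean was 1.55 higher, above the control median in 15 of 17 patients (adjusted p = 0.00018, and adjusted p = 0.098 with an estimated correlation). Mature neutrophil genes rose in 5 of 14 members, and in 7 adjusted over the list alone. Among them were the maltase MGAM (1.75 ± 0.33, adjusted p = 0.000182), the chemokine-like PROK2 (0.98 ± 0.31, adjusted p = 0.0229) and the fatty acid receptor FFAR2 (0.85 ± 0.20, adjusted p = 0.00212). PROK2 did not pass without the 6 controls with another code start (0.94, adjusted p = 0.0513). The mean of that list was 0.67 higher (adjusted p = 0.00598, and adjusted p = 0.222 with an estimated correlation). The immature list rose by 0.874 more than the mature list (permutation p = 0.0158), but with the erythroid mean as a covariate this gap was -0.595 (permutation p = 0.127). Platelet genes rose in 10 of 15 members, also when adjusted over the list alone, led by the fibrinogen receptor chain ITGA2B (1.58 ± 0.30, adjusted p = 0.000219, and 1.02 with the median over its probe sets), CLU (1.56 ± 0.32, adjusted p = 0.000607) and TREML1 (1.27 ± 0.24, adjusted p = 0.000174). The abundant platelet transcripts PF4 (0.63 ± 0.33, adjusted p = 0.187) and PPBP (0.49 ± 0.32, adjusted p = 0.307) did not pass. The platelet mean was 0.84 higher (adjusted p = 0.00119, and adjusted p = 0.158 with an estimated correlation). The median level of the members in each sample was 1.41 higher, while the median of the members' differences was 0.72.

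Cell cycle genes rose in 20 of 22 members, also when adjusted over the list alone, and the list mean lay above the control median in 17 of 17 patients. The topoisomerase TOP2A (1.51 ± 0.27, adjusted p = 9.3e-05), BIRC5 (1.40 ± 0.29, adjusted p = 0.000797) and CEP55 (1.33 ± 0.27, adjusted p = 0.000544), all used in dividing cells, were the largest. The cell cycle mean was 0.78 higher (adjusted p = 5.4e-05, and adjusted p = 0.098 with an estimated correlation). Across the 17 patients the erythroid mean went with the cell cycle mean (r = 0.631, permutation p = 0.00776, adjusted p = 0.0217, rho = 0.728, permutation p = 0.00131, adjusted p = 0.00714, r = 0.657 without the 2 farthest samples). It also went with the immature granulocyte mean (r = 0.725, permutation p = 0.00149, adjusted p = 0.00695, rho = 0.75, permutation p = 0.00073, adjusted p = 0.00511, r = 0.636 without the 2). The platelet mean went with the erythroid mean by r (r = 0.657, permutation p = 0.00251, adjusted p = 0.01, rho = 0.549, permutation p = 0.0236, adjusted p = 0.0601, r = 0.435 without the 2). In the 30 controls the erythroid and cell cycle means had r = 0.104 (permutation p = 0.588, adjusted p = 0.73) and rho = 0.038 (permutation p = 0.843, adjusted p = 0.874). Without the 2 farthest control samples r = 0.041. The immature granulocyte mean went with the erythroid mean in controls by rho only (r = 0.424, permutation p = 0.0249, adjusted p = 0.0536, rho = 0.476, permutation p = 0.0089, adjusted p = 0.0277, r = 0.519 without the 2). The platelet mean did so by both (r = 0.521, permutation p = 0.00591, adjusted p = 0.0184, rho = 0.556, permutation p = 0.00181, adjusted p = 0.00724, r = 0.543 without the 2). In all, 28 correlations were computed in this family, and the difference between groups was not tested. With the erythroid mean as a covariate the differences of the immature granulocyte (0.21), platelet (0.013) and cell cycle (0.35) lists no longer passed. That of the mature neutrophil list was 0.80, also no longer past the test.

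Receptors of NK cells fell. Of 12 measured members 10 fell and none rose, and 11 fell when adjusted over the list alone. Among them were CD160 (-1.31 ± 0.25, adjusted p = 0.000214), KLRF1 (-1.23 ± 0.19, adjusted p = 1.2e-05) and KLRB1, the CD161 lectin shared with innate-like T cells (-1.16 ± 0.15, adjusted p = 2.9e-07). The list mean was -0.80, from 8.28 ± 0.41 (SD) in controls to 7.47 ± 0.58 (adjusted p = 7.7e-05, and adjusted p = 0.0534 with an estimated correlation). In 11 of 17 patients it lay below the lowest control. The members NCR1 (-0.06 ± 0.09, adjusted p = 0.688) and CD244 (-0.30 ± 0.12, adjusted p = 0.0863) did not pass. NCR1 was dim, with means of 3.984 in sJIA and 4.046 in controls. Cytotoxic granule genes fell less than the NK receptors by 0.411 (permutation p = 0.00121). Of 11 members 4 fell, also when adjusted over the list alone, namely FGFBP2 (-0.89 ± 0.23, adjusted p = 0.0049), GZMK (-0.72 ± 0.17, adjusted p = 0.00251), GZMA (-0.52 ± 0.14, adjusted p = 0.00702) and the pore-forming PRF1 (-0.41 ± 0.14, adjusted p = 0.0428). Granzyme B (GZMB, -0.49 ± 0.26, adjusted p = 0.212) did not pass. The granule mean was -0.39 (adjusted p = 0.0468, and adjusted p = 0.372 with an estimated correlation). With the erythroid mean as a covariate it was -0.71 (adjusted p = 0.0383), with FGFBP2 at -1.42, GZMK at -1.19 and GZMA at -0.94, all past the test. The list did not pass without _x_at or _s_at probe sets (adjusted p = 0.0519) or with quantile normalization repeated (adjusted p = 0.0532). Leaving out any of 26 of the 47 arrays took this list's adjusted p over 0.05, to as much as 0.122 without patient 11. For PRF1 any of 15 arrays did so, to as much as 0.0801, again without patient 11, and it did not pass without the 6 controls (adjusted p = 0.0647).

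The T and B cell lists did not pass the test. T cell genes had a mean difference of -0.07 (adjusted p = 0.477, and adjusted p = 0.719 with an estimated correlation). The costimulator ICOS rose (0.50 ± 0.11, adjusted p = 0.000992). The receptor chain CD247 (-0.47 ± 0.12, adjusted p = 0.0067), CD2 (-0.32 ± 0.11, adjusted p = 0.0459) and BCL11B (-0.20 ± 0.07, adjusted p = 0.0304) fell. The other 12 of 16 T cell members did not pass, with the same counts adjusted over the list alone. None of the 16 B cell genes passed, on either adjustment (mean -0.055, adjusted p = 0.783). The NK receptor list was lower than the T cell list by a gap of -0.733 (permutation p = 9e-05). Plasma cell genes had 2 of 8 members higher, the syndecan SDC1 (0.75 ± 0.20, adjusted p = 0.00798) and the ectoenzyme CD38 (0.66 ± 0.18, adjusted p = 0.0101), and 3 when adjusted over the list alone. Their mean difference was 0.23 (adjusted p = 0.136). Leaving out any of 29 arrays took the adjusted p of CD2 over 0.05, to as much as 0.0897 without patient 11. BCL11B lost its call without patient 2 or patient 13 (up to 0.0589), and CD247 was at -0.19 (adjusted p = 0.0974) with the median over its probe sets.

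Dendritic cell genes fell in 5 of 9 members, with none rising, also when adjusted over the list alone. FCER1A, the high-affinity IgE receptor chain of myeloid dendritic cells and basophils (-1.30 ± 0.26, adjusted p = 0.000365), and the plasmacytoid dendritic cell receptors CLEC4C (-1.21 ± 0.21, adjusted p = 7.8e-05) and LILRA4 (-0.93 ± 0.18, adjusted p = 0.000341) were the largest. Without _x_at or _s_at probe sets FCER1A was at -0.65 (adjusted p = 0.0122), a smaller fall than those of CLEC4C and LILRA4. The dendritic cell mean was -0.54 (adjusted p = 5.4e-05, and adjusted p = 0.0534 with an estimated correlation). MHC class II genes fell in 4 of 9 members and in 6 when adjusted over the list alone. Among them were HLA-DPB1 (-0.46 ± 0.16, adjusted p = 0.0427), HLA-DMB (-0.45 ± 0.12, adjusted p = 0.00849) and HLA-DRA (-0.41 ± 0.10, adjusted p = 0.00485). The MHC class II mean differed by -0.35 (adjusted p = 0.00169, and adjusted p = 0.162 with an estimated correlation). None of the 11 MHC class I presentation genes passed (mean 0.06, adjusted p = 0.42). The same held for all 12 classical monocyte genes (mean 0.09, adjusted p = 0.473) and all 7 nonclassical monocyte genes (mean 0.04, adjusted p = 0.736, median of the members' differences -0.016), on either adjustment. The monocyte markers CD14 (0.64 ± 0.24, adjusted p = 0.0601) and CD163 (0.17 ± 0.18, adjusted p = 0.562) did not pass. HLA-DPB1 lost its call when any of 18 arrays was left out, with an adjusted p of up to 0.0979 without patient 15, and was at -0.81 (adjusted p = 0.0295) without _x_at or _s_at probe sets. It also did not pass without the 6 controls with another code start (adjusted p = 0.0684). With the median over members in place of the mean, the dendritic cell (-0.25, adjusted p = 0.0525) and MHC class II (-0.34, adjusted p = 0.0589) lists did not pass. Among genes above the median level the dendritic cell difference was -1.06 (adjusted p = 5.4e-05).

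In the IL-6 and STAT3 response list, the Fc receptor FCGR1A (1.74 ± 0.22, adjusted p = 2.4e-07), the cytokine signalling inhibitor SOCS3 (1.42 ± 0.17, adjusted p = 1.8e-07), the kinase PIM1 (0.47 ± 0.08, adjusted p = 3.1e-05) and JUNB rose. The other 5 of 9 did not pass, and 5 rose when adjusted over the list alone. Its mean was 0.53 higher (adjusted p = 5.4e-05, and adjusted p = 0.0534 with an estimated correlation), and 12 of 17 patients lay above the highest control. The S100 alarmins, calcium-binding proteins that myeloid cells release, rose in 5 of 6 members on either adjustment. They were led by S100P (1.76 ± 0.38, adjusted p = 0.00111), S100A9 (1.07 ± 0.19, adjusted p = 8.5e-05) and S100A12 (1.07 ± 0.23, adjusted p = 0.00092). Their mean was 0.83 higher (adjusted p = 7.7e-05, and adjusted p = 0.114 with an estimated correlation). In the macrophage scavenging and iron list, HP, the hemoglobin-binding haptoglobin that neutrophil precursors also make (2.42 ± 0.29, adjusted p = 1.2e-07), the efferocytosis receptor MERTK (0.71 ± 0.17, adjusted p = 0.00378) and ferritin light chain FTL (0.28 ± 0.09, adjusted p = 0.0194) rose and 3 of 6 did not pass, on either adjustment. That mean was 0.66 higher (adjusted p = 5.4e-05, and adjusted p = 0.158 with an estimated correlation). The median level of the members in each sample was 1.17 higher, while the median of the members' differences was 0.30. MERTK was at 0.11 (adjusted p = 0.0546) without _x_at or _s_at probe sets, and FTL at 0.23 (adjusted p = 0.0519) with arrays centred on the median gene. With the 7 main cell type means as covariates none of these lists passed, and the S100 difference was -0.12.

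In the inflammasome and IL-1 family list, IL1B (0.86 ± 0.28, adjusted p = 0.0319), its antagonist IL1RN (0.75 ± 0.17, adjusted p = 0.00142, and 0.43 without _x_at or _s_at probe sets), the caspase CASP5 (0.72 ± 0.23, adjusted p = 0.0283) and NLRC4 rose. The IL-18 receptor chain IL18RAP, which NK cells carry, fell (-0.76 ± 0.24, adjusted p = 0.026), and 13 of 18 did not pass. Adjusted over the list alone, 5 rose and 1 fell, and the mean was 0.23 higher (adjusted p = 0.0338, and adjusted p = 0.417 with an estimated correlation). The list also did not pass with the median over probe sets (adjusted p = 0.07), without _x_at or _s_at probe sets (adjusted p = 0.0677), with centring (adjusted p = 0.108) or with the median over members (0.086, adjusted p = 0.471). The cytokines IL18 (-0.26 ± 0.21, adjusted p = 0.432), TNF (0.34 ± 0.22, adjusted p = 0.302) and IL6 (0.29 ± 0.10, adjusted p = 0.0526) did not pass. IL6 was dim, with means of 3.902 in sJIA and 3.615 in controls. It lay near the threshold and passed with RNA quality as a covariate (0.33, adjusted p = 0.0208), with array weights (0.33, adjusted p = 0.016) and when any of 8 arrays was left out. Toll-like receptor genes rose in 2 of 12 members on either adjustment. These were the lipopeptide receptor TLR1 (0.59 ± 0.13, adjusted p = 0.00165) and the adaptor MYD88 (0.40 ± 0.11, adjusted p = 0.0137), and the mean was 0.21 higher (adjusted p = 0.0468, and adjusted p = 0.49 with an estimated correlation). NF-kB targets rose in 3 of 13 on either adjustment. These were the chemokines CXCL2 (1.24 ± 0.38, adjusted p = 0.022) and CXCL3 (0.78 ± 0.23, adjusted p = 0.0175) and the inhibitor NFKBIA (0.79 ± 0.20, adjusted p = 0.00636), and the mean was 0.45 higher (adjusted p = 0.0349, and adjusted p = 0.519 with an estimated correlation). CXCL3 was dim, with means of 4.13 in sJIA and 3.35 in controls. Immediate early genes, which also respond to the handling of blood, rose in 4 of 12 on either adjustment. FOS was at 1.02 ± 0.34 (adjusted p = 0.0331), JUN at 1.00 ± 0.27 (adjusted p = 0.00807) and DUSP1 at 0.85 ± 0.26 (adjusted p = 0.0195, and 0.54 with the median over its probe sets). Their list mean was 0.48 higher (adjusted p = 0.02, and adjusted p = 0.346 with an estimated correlation). The median level of the members in each sample was 0.87 higher, while the median of the members' differences was 0.31. In the list of genes mutated in hemophagocytic lymphohistiocytosis, an inherited hyperinflammation, STXBP2 rose (0.65 ± 0.16, adjusted p = 0.00336, and 0.34 with the median over its probe sets), PRF1 fell and 6 of 8 did not pass on either adjustment. The mean difference was 0.027 (adjusted p = 0.659), and the median of the members' differences was -0.0095. Some of these calls lay near the threshold. With the preset correlation camera did not pass the NF-kB (adjusted p = 0.0652) and IL-1 (adjusted p = 0.0504) lists. The Toll-like receptor list had an adjusted p over 0.05 when any of 30 arrays was left out (up to 0.101, without patient 11). The NF-kB list lost its call without patient 1, 6, 11, 15 or 17 (up to 0.0922), and the IL-1 list without patient 6, 8, 11 or 15 (up to 0.0917). Among genes, IL1B did so without patient 1, 6, 11 or 17 (up to 0.0672) and CASP5 without patient 2, 4, 8 or 16 (up to 0.0612). IL18RAP did so without patient 16 (0.0508) and FOS without patient 1, 4, 6, 8, 11 or 15 (up to 0.0635). CXCL2 was at 0.14 with either other choice of probe sets (adjusted p of 0.0783 and 0.0831).

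Interferon response genes rose in part of the list and varied widely among patients. Of 20 type I interferon response genes 4 rose, and 8 when adjusted over the list alone. Among them were IFI27 (2.14 ± 0.52, adjusted p = 0.00308), the antiviral RSAD2 (0.91 ± 0.28, adjusted p = 0.0219) and OASL (0.84 ± 0.27, adjusted p = 0.0316). IFIT1 (0.43 ± 0.38, adjusted p = 0.476) and MX1 (0.54 ± 0.23, adjusted p = 0.109) did not pass. The mean was 0.56 higher (adjusted p = 0.0378, and adjusted p = 0.417 with an estimated correlation), with 10 of 17 patients above the control median. In 6 patients it lay above the highest control. In the interferon gamma response list ANKRD22 (1.62 ± 0.31, adjusted p = 0.000312), the complement inhibitor SERPING1 (1.06 ± 0.31, adjusted p = 0.0147) and BATF2 (0.43 ± 0.15, adjusted p = 0.0472) rose. The other 10 of 13 did not pass on either adjustment, including the chemokines CXCL9 (-0.09 ± 0.13, adjusted p = 0.697) and CXCL10 (0.27 ± 0.44, adjusted p = 0.716). The mean of that list was 0.32 higher, with 9 of 17 patients above the control median (adjusted p = 0.0378, and adjusted p = 0.519 with an estimated correlation). Both list means spread more in patients, with SDs of 1.23 against 0.41 for type I and 0.73 against 0.24 for interferon gamma. The permutation test takes these spreads as equal, so its p-values for both means may be too small. The same holds for limma's SEs and p-values of genes such as IFI27, with SDs of 2.97 in patients and 0.29 in controls. The type I call was lost without control 16 or 29 or without patient 2, 3, 8, 9, 10, 13, 15 or 16 (adjusted p up to 0.105). The interferon gamma call was lost without control 16 or 29 or without patient 2, 8, 9, 10, 13 or 15 (up to 0.126, with a difference of 0.19 without patient 2). Both calls were also lost with the RNA quality ratios as covariates (adjusted p = 0.078 for each) and with arrays centred on the median gene (0.0591 for type I, 0.0881 for interferon gamma). Type I lost its call among genes above the median level (0.0802). OASL lost its call with the RNA quality ratios (0.0608), without the 6 controls (0.0518) and without patient 2, 8, 9, 13, 15 or 16 (up to 0.0696), and BATF2 when any of 28 arrays was left out (up to 0.0882, without patient 15). BATF2 also lost it with the RNA quality ratios (0.0647) and without the 6 controls (0.0803), among other settings.

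Of the 27 lists, 8 passed the test of spread with patients differing more from each other than controls did, and none passed it with a smaller spread in patients. The spread of the erythroid mean was the widest, from 4.58 to 9.37 in patients against 4.65 to 6.29 in controls. The SD ratio was 4.38 (permutation test on absolute deviations from the group median, adjusted p = 0.00027). The ratios were 3.10 for the interferon gamma response (adjusted p = 0.00182), 2.97 for the type I interferon response (adjusted p = 0.000405), and 2.77 for MHC class II (adjusted p = 0.00873). They were 2.34 for heme synthesis (adjusted p = 0.00108), 2.32 for MHC class I presentation (adjusted p = 0.00216), 1.71 for B cell genes (adjusted p = 0.0323) and 1.59 for immature granulocyte genes (adjusted p = 0.0129). Type I interferon and MHC class I means went together across patients (r = 0.724, permutation p = 0.00091, adjusted p = 0.0051, rho = 0.723, permutation p = 0.00153, adjusted p = 0.00714, r = 0.754 without the 2 farthest samples). In controls they did so by r only (r = 0.458, permutation p = 0.0113, adjusted p = 0.0264, rho = 0.286, permutation p = 0.126, adjusted p = 0.251, r = 0.189 without the 2). With the median over members in place of the mean, 6 of the 8 lists lost their call in the test of spread and only 2 passed. The B cell call was lost in 5 of 17 omissions of a patient, with an adjusted p of up to 0.121 without patient 15. The mature neutrophil ratio of 2.0 (adjusted p = 0.0726) passed in 7 of them.

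**Figure D3:**
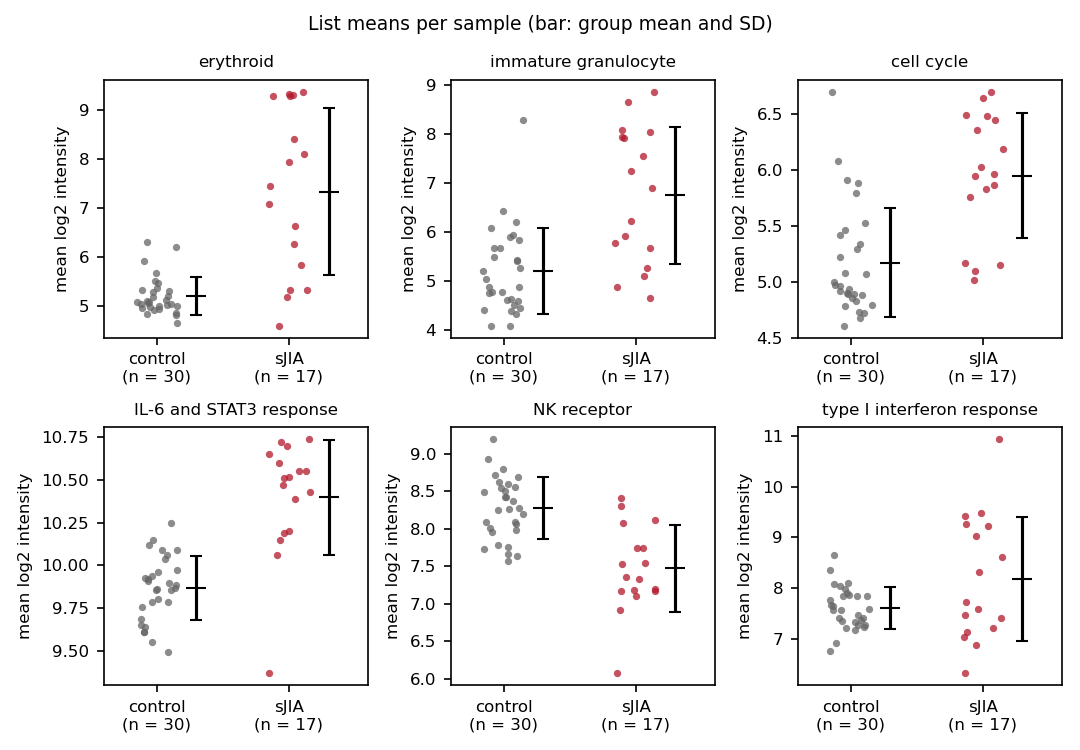
Points are samples, and the y axis is the mean log2 intensity over the members of 6 lists in controls (gray, n = 30) and sJIA (red, n = 17), with bars for the group mean and SD. In the erythroid list 11 of 17 patients lie above the highest control, and in the IL-6 and STAT3 response list 12 do.

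Neither measure of RNA quality passed a test of a difference between the groups. The log2 ratio of 3' to 5' signal of the Affymetrix control probe sets was 0.651 ± 0.346 (SD) in sJIA and 0.644 ± 0.355 in controls for GAPDH (permutation p = 0.949). For ACTB this log2 ratio was 3.42 ± 0.761 against 3.57 ± 0.587 (permutation p = 0.461). With both ratios as covariates 15 lists passed, and the inflammasome (adjusted p = 0.0505), Toll-like receptor (adjusted p = 0.118) and both interferon lists did not. The arrays of patients 11 and 14 had the lowest median correlations with the other arrays, 0.959 and 0.964. Without them 4253 genes passed, 909 of them with at least a 1.5-fold change. Then 18 lists passed, the cytotoxic granule list being lost (-0.24, adjusted p = 0.203). No patient had a label code of the kind of the 6 controls, so no comparison within that kind was possible. Comparisons within the code starts that patients and controls shared were not run. Without these 6 controls the cytotoxic granule, Toll-like receptor, type I interferon, interferon gamma and NF-kB lists no longer passed and 14 lists did.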

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

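Probe sets with several gene symbols or none in the annotation used here entered none of the comparisons, and were tested only in the fit of all probe sets. Of 13522 such probe sets, 1048 passed in limma at an adjusted p under 0.05, 404 higher and 644 lower in sJIA than in the control samples. Of the 96 that changed by at least 2-fold, 71 were higher and 25 lower, and the 10 largest changes were all rises, of 2.55 to 3.49 on the log2 scale. The 1048 were 7.75% of those tested, against 11.2% of the probe sets with 1 gene symbol. Among those rises were 3 probe sets shared by the fetal globins HBG1 and HBG2, all with names ending in _x_at. The genes behind the others are not named here.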

How the results depend on the processing

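All alternatives but 1 were chosen before the data were examined; leaving out the arrays of patients 11 and 14 was chosen after seeing the data. Across 12 settings that changed the probe set rule, filter, scaling, constant, variance model, weights, RNA quality term or samples, 71 of 90 named genes kept their direction and their side of the threshold in each setting that measured them. Of 1064 values 1030 kept both, 30 lost the call, 2 gained it and 2 changed sign, CA1 (-0.0177) and CD163 (-0.128) without _x_at or _s_at probe sets, which leaves them different probe sets. Across 10 such settings 15 of 27 lists kept both, with 26 of 270 values losing the call and 1 gaining it, and 14 to 19 lists passed. Another 8 values changed sign, all of lists not past the test. These were the hemophagocytic list with the median over probe sets (-0.029), centring (-0.0225), RNA quality ratios (-0.00533) and the median over members (-0.101), and the B cell list without the 6 controls (0.037) and with RNA quality ratios (0.0463). The others were the progenitor list with the median over probe sets (0.0256) and the nonclassical monocyte list with centring (-0.00942). camera, which compares with other genes, put the hemophagocytic list (0.0271) below them with either correlation. The counts of genes ranged in these settings from 2338 to 4253, and from 474 to 909 with the 1.5-fold limit. They moved further in others. All probe sets tested singly gave 5657 and 1498 of 54613 tested. Drawing 17 controls at random gave as few as 963 and 460 and as many as 2681 and 818 over 20 draws, with fewer samples. With the erythroid mean as a covariate, 114 genes, 89 of them with the 1.5-fold limit, and 4 of 26 lists passed, and FECH (-0.0922) and the T cell (0.0251), B cell (0.463) and hemophagocytic (-0.0325) lists changed sign. With the 7 cell type means as covariates, 1 gene passed, 1 with the limit (IL13RA1, -0.968, named after its value was seen), and 0 of 20 lists. There MYB (-0.0484), FECH (-0.00348), IL1B (-0.218), IL1RN (-0.157), IL18RAP (0.0538), S100P (-0.118), S100A9 (-0.0233), S100A12 (-0.23), FTL (-0.144), CXCL3 (-0.0869), TNF (-0.537) and the plasma cell (-0.0155), hemophagocytic (-0.117), inflammasome (-0.0626), Toll-like receptor (-0.116), S100 (-0.115) and NF-kB (-0.267) lists changed sign. Standard errors grew in both covariate settings, and the cause of the lost calls was not tested beyond that. camera with an estimated correlation passed 0 lists (17 with the preset one), and the spread test on medians over members passed 2, for causes that were not tested. Of lists not past the spread test, the SD ratio crossed 1 with those medians for dendritic cell (0.961), progenitor (1.18) and IL-6 (0.737) genes, and without patients 11 and 14 for T cell (0.84), dendritic cell (0.97) and S100 (0.761) genes. Leaving out each sample gave 2166 to 4050 genes, 614 to 880 with the limit, 13 to 19 lists, and B cell differences from -0.147 to 0.053. Leaving out each patient, but no control, gave 7 to 9 lists for the spread. No paired analysis was possible because the labels give no numbers that pair patients with controls. Signal near the background limits dim genes, as no detection calls were used here.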

Other observations

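The tests of 8 further lists were chosen only after the main results had been seen, and so were those on single patients, on all lymphocytes and on mature neutrophils below, and the platelet term. The list written for innate-like T cells (mucosal-associated invariant T cells and their relatives) was lower in sJIA, but not all its members are particular to them. Of 12 measured members 7 fell, among them the cytokine receptors IL23R (-0.85 ± 0.17, SE, limma adjusted p = 0.000365) and IL7R (-0.37 ± 0.07, adjusted p = 0.000168). IL23R lay near the low end of the intensities, with means of 2.83 in sJIA and 3.68 in controls. NCR3, another of the 7, also stands in the NK receptor list. The chemokine receptor genes CXCR6 (-0.73 ± 0.20, adjusted p = 0.00894) and CCR6 and the transcription factor ZBTB16 (-0.49 ± 0.14, adjusted p = 0.0102) fell too. The list mean was -0.28, below the control median in 17 of 17 patients (permutation, adjusted p = 0.00064 over the 8 lists, and adjusted p = 0.206 with an estimated correlation). SLC4A10, a marker of these cells, was near the low end of the intensities and did not pass (0.016 ± 0.036, adjusted p = 0.805). Genes of glycolysis rose in 9 of 18 members. Examples were PKM (0.57 ± 0.14, adjusted p = 0.0034), GAPDH (0.56 ± 0.12, adjusted p = 0.000979), HK1 (0.54 ± 0.12, adjusted p = 0.00112) and ENO1 (0.52 ± 0.14, adjusted p = 0.0108), and the list mean was 0.31 higher, above the control median in 15 of 17 patients (adjusted p = 0.00104, and adjusted p = 0.206 with an estimated correlation). Of the heat shock list 2 of 11 rose, HSPA6 (0.61 ± 0.21, adjusted p = 0.0364) and HSPB1 (0.48 ± 0.15, adjusted p = 0.0229), and the mean was 0.13 higher (adjusted p = 0.0166, and adjusted p = 0.758 with an estimated correlation).

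The lists of oxidative phosphorylation (0.059, adjusted p = 0.51), proteasome (0.064, adjusted p = 0.195), ribosomal protein (-0.087, adjusted p = 0.261) and basophil and mast cell genes (-0.149, adjusted p = 0.556) did not pass the permutation test. Glucocorticoid response genes had a mean difference of -0.0424 (adjusted p = 0.578), with FKBP5, which these hormones induce, at -0.04 ± 0.11 (limma adjusted p = 0.856). With the erythroid mean as a covariate the largest differences left were those of FAM20A (2.16), ALDH1A1 (-2.00), the vasodilator peptide ADM (1.99) and PRSS23 (-1.96). They had limma adjusted p of 0.000164, 0.00101, 0.000557 and 0.000991 and were named after their values were seen. The cell cycle list differed by 0.35 with the erythroid mean as a covariate (permutation p = 0.0892) and by 0.78 without it, in a setting that also ended the calls of 13 other lists.

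The rise of erythroid genes may come from red cells or their precursors in the mononuclear fraction of patients. Differences in RNA quality are argued against as the whole cause, since the list differed by 1.98 with both ratios as covariates (permutation p = 2e-05) against 2.13 without. A few patient arrays are argued against too, since the group medians differed by 2.37 and 11 of 17 patients lay above the highest control. Whether the cells were nucleated precursors or anucleate red cells cannot be told apart. GATA1, TAL1, GFI1B and TFRC, used in nucleated precursors, were higher by a mean of 0.643 (permutation p = 7e-05). But GATA1 and TFRC also stand in the erythroid list itself, and platelets share some of the genes. With the platelet mean as a covariate the difference was 0.165 (permutation p = 0.0623). That mean went with the erythroid mean in patients (r = 0.657), so neither value decides the question. Patients 4 to 9, whose label codes began like those of most controls, had erythroid means of 5.839, 6.257, 5.311, 7.069, 5.324 and 5.174. The highest control had 6.292. All other patients but patient 14 (4.582) lay above that control, so the rise went with the code start. What the code start stands for is not given, and its effect was not tested. The disease, the way cells were separated and a batch that the labels do not give stay open.

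The fall of NK receptors was set against a lower share of all lymphocytes, which is argued against, since the NK receptor list was lower than the mean of the T and B cell lists by a gap of -0.74 (permutation p = 0.00018). RNA quality as the whole cause is argued against by a difference of -0.806 with both ratios as covariates (permutation p = 1e-05). A lower share of NK cells and lower receptor transcripts per NK cell both stay open. So does a fall in T cells that share some of these receptors, such as KLRB1. The list written for innate-like T cells was lower too (-0.28). Granule genes, which T cells share, fell less than the receptors by 0.411 (permutation p = 0.00121).

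The rise of immature granulocyte genes may come from light granulocytes that stay with the mononuclear cells. RNA quality as the whole cause is argued against by a difference of 1.44 with both ratios as covariates (permutation p = 5e-05). Mature neutrophils cannot be told apart from immature cells here. The immature list rose by 0.874 more than the mature list (permutation p = 0.0158), but with the erythroid mean as a covariate that gap was -0.595 (permutation p = 0.127). A release of immature cells from the marrow, handling of the blood and an unnamed batch stay open as untested.

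Chance as the source of the gene counts is argued against, as far as 100 splits of the 47 samples into 17 and 30, the real one included, can tell. Of these, 1 gave 2838 genes and 1 gave 695 with the 1.5-fold limit, the real split in both. The highest other split gave 1 gene in each, and 96 splits gave no gene past the test.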
